A study of Homo sapiens with 5 samples.

How the data were processed

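Total RNA was measured in 5 cultures of 293T cells, a human embryonic kidney line that carries the SV40 large T antigen and takes up plasmids readily. Per the labels, 3 cultures were transfected with a plasmid that carried Aire under a CMV promoter and 2 with the same kind of plasmid without an insert, at 6 µg of plasmid for each 10 cm plate. RNA was extracted 48 h later, 6 µg was made into biotin-labelled cRNA per the labels, and each culture was hybridised to its own Affymetrix 3' expression array. The series design calls the cultures with Aire biological replicates, so they were treated as separate cultures, and the controls were treated the same way. The labels give neither the species nor the extent of the Aire cDNA.

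The authors deposited linear probe set intensities for all 5 arrays in a common table. How the probes were summarised and how the arrays were scaled to one another is not given in the sources used here. The medians of the 5 arrays spanned 7.09% of one another and their upper quartiles 4.37%, both within the 10% fixed as the limit for taking values as already normalized, so the deposited intensities were not normalized again. The lowest deposited intensity was 8.88 and the highest 24613, which shows that no log had been taken. All sample columns were used. Hybridisation and scan dates were not used here. The 18 hybridisation spike-in probe sets split the arrays at the widest gap of their mean log2 intensity into Aire replicate 3 and control replicate 2 on one side and the other 3 arrays on the other, and a fit with a block on this split was added after the data were seen. A batch that the spike-ins do not mark could not be tested. The number of arrays limits the precision, and with 3 arrays against 2 an exact permutation test cannot go below a p of 0.1.

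The table held 54675 probe sets. The 62 control probe sets were left out, and the other 54613 were tested on log2(intensity + 16), without a filter on dim probe sets. A fold change is therefore on the log2(intensity + 16) scale, which understates the change of genes of low level. The platform's annotation, which can be old, gave 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721. Gene identifiers were looked up in a RefSeq gene table of the assembly GRCh38.p14, which changed 0 symbols and was also used for which genes neighbour each other, and no coordinate is printed. Each of 19775 genes was represented by the probe set with the highest mean over all 5 arrays among those with exactly 1 symbol, and 10523 of these genes had more than 1 probe set. No gene was named from a probe set with several symbols. Among the genes named, ACTB, GAPDH, GGTLC1, HLA-E, MT1G, MT1X, SRSF7, SLC2A3, JUN, NR4A2, CYP1A2, GH1 and KRT33A are represented by a probe set whose name marks it as able to cross-hybridise. Others are represented by a probe set whose name marks it as shared by several transcripts, among them TKTL1, S100A8, ALOX12, MYC, KLF4, HSPB8, NPPA, HP, APOA2 and TF. Probe sets of plain name carry neither mark.

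Arrays labelled Aire were compared with the controls by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided, 3 residual degrees of freedom), with Benjamini-Hochberg adjustment over all 54613 probe sets and a threshold of 0.05. Values are given as means ± SD of the intensities, and log2 folds with their standard errors. The design, the alternatives, the rule for named genes and 36 gene lists were fixed before the data were examined. The lists cover 11 groups of tissue-restricted genes, the autoantigens of AIRE deficiency in people, genes tied to AIRE as protein partners, stress, signalling and housekeeping pathways, and markers of 5 other cell types. Of 953 different genes on the lists, 845 were measured. The lists were tested with limma's camera on the representative probe sets with a preset correlation between genes of 0.01, and adjusted over the 36 lists. An estimated correlation and limma's fry were alternatives. Within a list, the adjusted p of each member was computed over all probe sets and over the list alone. The union of the tissue lists was tested with camera and, as the share of genes that rose, with Fisher's exact test against all other genes. Its median was also set among 10000 random gene lists of the same size matched on mean level.

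The genes named are AIRE, the 12 genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05, separate groups and a level in the higher group at or above the 25th percentile of all probe sets. Where fewer passed, the places were filled by the smallest unadjusted p under the same other conditions. Up to 4 members of each list were added by the smallest unadjusted p, together with the fixed panel of KRT14, S100A8, S100A9, IGFL1, INS, IVL, ACTB and GAPDH. The level of 1 gene that the rule names is not given, since it bears on the sex of the cells. Genes or probe sets outside this rule are named as chosen after their values were seen.

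The alternatives were quantile normalization, median centring, leaving out dim probe sets, a pseudocount of 1 or 64, eBayes with trend or robust, the replicate number as a block, leaving out each array in turn, array quality weights, the mean of all probe sets of a gene, 2 bins of level at the median, and a threshold on unadjusted p with a fold of at least 2. Alternatives added after the data were seen are named as such where they appear. The fit was tested on simulated data of 3 arrays against 2 with 54613 probe sets. It called 51% of 100 probe sets changed by a log2 fold of 1 and 93% of 100 changed by a log2 fold of 2, with 6 calls among unchanged probe sets, and 0 calls where nothing had changed. A list of the 19775 genes shifted by 0.3 was called with an adjusted p of 3.41e-23, and 0 other lists were. The simulated probe sets were drawn independently, without correlation between genes or differences between arrays. The simulation therefore does not show how many false calls the fit or camera makes in these data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.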

Results

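Transcript levels were measured on 5 arrays of 293T cells, 3 from cultures that received a plasmid with Aire and 2 from cultures that received the empty plasmid. AIRE is a transcriptional regulator of the thymus, where it takes part in the expression of tissue-restricted genes in medullary epithelial cells. The design asks which transcripts change when Aire is expressed in a cell line of another origin. The median intensity was 67.8, 70.3 and 72.6 on the arrays labelled Aire and 71.3 and 70.6 on the controls.

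The AIRE transcript itself was measured first. The only probe set of AIRE on the array read 112 ± 18.5 (SD, n = 3) on the arrays labelled Aire and 97.0 ± 18.1 (n = 2) on the controls. The log2 fold was 0.18 with a standard error of 0.16 and a 95% interval from -0.21 to 0.58, and the limma adjusted p was 0.939. AIRE was therefore not measurably higher in the arrays labelled Aire. The labels do not say whether the plasmid carried the sequence that this probe set detects, so the value neither bears out nor contradicts them, and the arrays are called by their label throughout.

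Compared with the controls, 15 probe sets rose in the arrays labelled Aire and 0 fell (limma, adjusted p under 0.05), and each of the 15 was higher on all 3 arrays labelled Aire than on both controls. At gene level 5 genes rose and 0 fell. GCNA, a nuclear protein of germ cells, rose from 48.1 ± 3.71 (n = 2) to 227 ± 25.5 (n = 3), a log2 fold of 1.92 ± 0.11 (SE, adjusted p = 0.0316). TKTL1, a transketolase-like protein, rose from 113 ± 1.09 to 452 ± 57.3, a log2 fold of 1.86 ± 0.12 (adjusted p = 0.0422). S100A8, a calcium-binding protein of neutrophils and stressed keratinocytes, rose from 20.4 ± 2.15 to 97.6 ± 11.1, a log2 fold of 1.64 ± 0.11 (adjusted p = 0.0422). ALOX12, a lipoxygenase of platelets and skin, rose from 43.9 ± 4.16 to 123 ± 4.38, a log2 fold of 1.22 ± 0.09 (adjusted p = 0.0439). DNAH17, a dynein heavy chain of the sperm tail, rose from 84.8 ± 1.07 to 216 ± 12.4, a log2 fold of 1.20 ± 0.08 (adjusted p = 0.0437). The second probe set of TKTL1 gave a log2 fold of 1.12 that did not pass (adjusted p = 0.395), while the second probe sets of S100A8 and DNAH17 gave 0.04 and 0.00.

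The other probe sets that rose could not each be given to 1 representative gene. NEFH, the heavy neurofilament chain, rose on 1 of its probe sets from 17.0 ± 1.78 (n = 2) to 78.2 ± 5.38 (n = 3), but its brighter probe set gave a log2 fold of 1.01 that did not pass (adjusted p = 0.689). Another 6 probe sets are annotated to several symbols each. For 3 of these all symbols belong to the GAGE family of cancer-testis antigens, and their log2 folds were 2.61, 2.70 and 2.17. The brightest rise was of a probe set annotated to 5 symbols of the SPDYE family, which read 722 ± 106 on the arrays labelled Aire and 46.1 ± 16.5 on the controls, a log2 fold of 3.59. The last 3 probe sets carry no symbol in the annotation. These probe sets lie outside the rule for named genes and are described here after their values were seen.

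Of the genes next in order of p, none passed the threshold. KRT14, a keratin of basal keratinocytes, had a log2 fold of 1.29 (limma adjusted p = 0.147), SERPIND1, a plasma protease inhibitor made in the liver, 2.40 (adjusted p = 0.155), SOST, which encodes the bone protein sclerostin, 1.01 (adjusted p = 0.0679) and MYH6, the alpha heavy chain of cardiac myosin, 1.10 (adjusted p = 0.243). GGTLC1, S100A7 and RSPH1, the last a protein of cilia, had log2 folds of 1.08, 0.63 and 0.65. The panel genes S100A9, INS and IVL stood at 0.14, -0.04 and 0.04, and ACTB and GAPDH at 0.11 and -0.10, with adjusted p from 0.898 to 0.994.

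**Figure D1:**
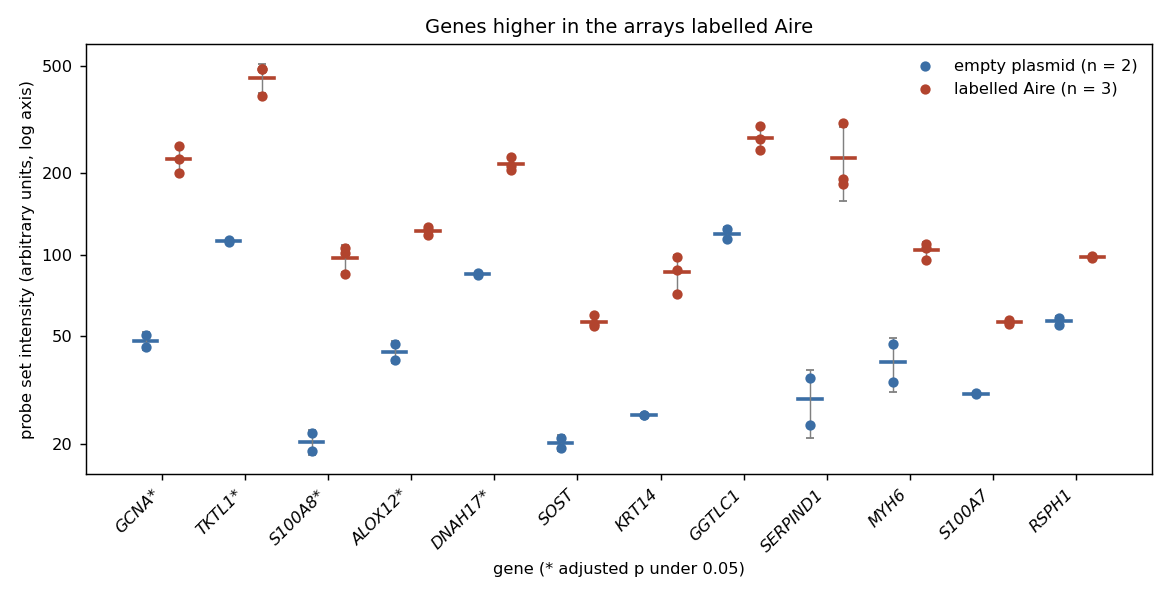
Probe set intensity on a log axis in arbitrary units for the 12 genes with the strongest evidence of a higher level, with a point for each array, a bar at the group mean and whiskers of 1 SD (2 controls and 3 arrays labelled Aire). The 5 genes marked with an asterisk rose, and in all 12 every array labelled Aire lies above both controls, as the rule that chose them required.

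On the lower side no gene passed, and the smallest adjusted p was 0.294. It belonged to GPR155, which read 100 ± 0.891 (n = 3) against 194 ± 30.2 (n = 2), a log2 fold of -0.85. The linker histone gene H1-2 (log2 fold -0.96, limma adjusted p = 0.312), the small heat shock gene HSPB8 (-0.98, 0.364), the Hippo pathway co-activator WWTR1 (-0.56, 0.339) and MYC (-0.67, 0.463) followed. MKX, TC2N, PRKAR2B, PELI2, DOCK4 and GUCY1B1 lay between -0.65 and -0.50. The last of these 12 genes, a noncoding RNA that did not pass either, is left out because its level bears on the sex of the cells. The other probe sets of GPR155 had -0.12 and -0.19, that of HSPB8 -0.10 and those of WWTR1 0.33 and -0.22. At an unadjusted p under 0.05, 1588 probe sets were higher and 1713 lower, while among the representative probe sets of genes 993 were higher and 599 lower, and with a fold of at least 2 besides, 49 were higher and 2 lower. Without Aire replicate 1, 2 or 3 or without control replicate 1 the count of probe sets that rose was 0, and without control replicate 2 it was 422 beside 173 that fell, while all 15 kept a positive log2 fold in each of these fits. A pseudocount of 64 also gave 0. The positive folds of the 15 were fixed in advance, since each was higher on every array labelled Aire than on both controls. At an unadjusted p under 0.05, leaving out Aire replicate 1, 2 or 3 gave 939, 843 and 2589 probe sets higher and 855, 886 and 3331 lower.

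The arrays did not separate by plasmid alone. Control replicate 1 stood apart from the other 4 arrays along the first principal component (46.1% of the variance, 53.1 against -18.8 to -4.3), and 720 probe sets differed over 2-fold between the controls. On the second component Aire replicate 3 lay near control replicate 2 (scores of 31.3 and 20.8), away from Aire replicates 1 and 2 (-22.3 and -23.0). The 18 hybridisation spike-in probe sets parted the arrays in a similar way, with geometric mean intensities of 1085 on Aire replicate 3 and 1041 on control replicate 2 against 2262, 2127 and 1792 on Aire replicates 1 and 2 and control replicate 1. With a block on these groups, chosen after the data were seen, 2 probe sets rose and 0 fell (limma, 2320 and 3179 at an unadjusted p under 0.05). Aire replicates 1 and 2 were the closest pair, with r = 0.9964 across probe sets and 8 probe sets over 2-fold apart, and were not identical. The 3' over 5' signal of the ACTB and GAPDH control probe sets, a sign of RNA integrity, averaged 1.04, 1.06 and 1.62 (log2) on Aire replicates 1, 2 and 3 and 0.80 and 0.92 on the controls, so it was higher in the arrays labelled Aire. Of 17 control probe sets of human transcripts, 4 were lower and 0 higher on every array labelled Aire than on both controls, where chance gives 10% in each direction. Several of the 17 read the same transcript, so they are not separate units and the count decides nothing.

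**Figure D2:**
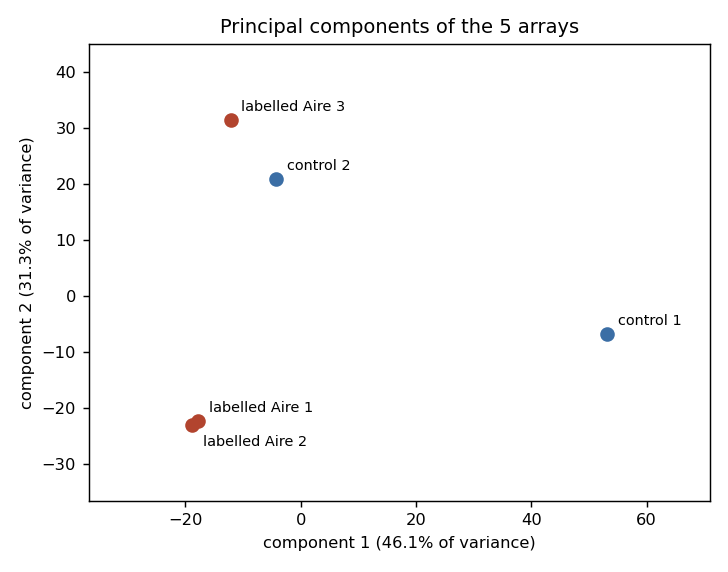
Scores of the 5 arrays on the first 2 principal components of the log2 intensities, with the share of the variance on each axis. Control replicate 1 stands alone on the first axis, and the second sets Aire replicates 1 and 2 apart from Aire replicate 3 and control replicate 2.

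Genes of skin and muscle rose as groups, while the call of the hair list was lost when neighbouring paralogs were counted once. Of 32 measured genes of epidermal keratinisation, 9 rose and 0 fell when adjusted over the list alone, and 1 rose over all probe sets. Among them were S100A8, KRT14, S100A7 and IGFL1, a small secreted protein of skin, which read 143 ± 20.4 (n = 3) against 73.8 ± 1.23 (n = 2), a log2 fold of 0.81. The list's median log2 fold was 0.16 (limma camera adjusted p = 3.58e-07), and its adjusted p = 0.590 with an estimated correlation. Of 20 measured genes of hair and oral keratins and tooth, 5 rose and 0 fell adjusted over the list alone, among them the hair keratins KRT33A (0.95), KRT33B (0.85), KRT31 (0.75) and KRT85 (0.67). The first 3 are neighbouring paralogs, so their rises may not be separate, and the probe set of KRT33A is of the kind that can cross-hybridise. The list's median was 0.08 (camera adjusted p = 0.00713), and its adjusted p = 0.590 with an estimated correlation. With only the brightest gene of each run of neighbouring paralogs, chosen after the data were seen, 14 hair genes were left with a median of 0.03 and the call was lost (camera adjusted p = 0.165). Of 34 measured muscle genes, 3 rose and 0 fell adjusted over the list alone. These were MYH6, the natriuretic peptide gene NPPA (log2 fold 0.49) and TTN, which encodes the sarcomere protein titin (0.83). The other 5 probe sets of TTN lay between -0.06 and 0.05. The list's median was 0.17 (camera adjusted p = 1.44e-05), and its adjusted p = 0.590 with an estimated correlation. Muscle genes also differed between the controls, with a median 0.12 higher in control replicate 1. Without control replicate 2 the medians of the epidermal, hair and muscle lists were 0.10, 0.04 and 0.11, and that of the hair list was 0.14 without Aire replicate 1, 0.02 without Aire replicate 3 and 0.11 without control replicate 1. The hair list lost its call without Aire replicate 3 (adjusted p = 0.0852), and the hair and muscle lists lost theirs without control replicate 2 (0.419 and 0.261). The muscle list also lost it when dim probe sets were left out (0.0651).

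Genes of the p53 response rose as a list, while no single member passed. Of 22 measured targets, 18 had a positive log2 fold and the median was 0.43, but 0 rose adjusted over the list alone (camera adjusted p = 9.66e-05, and adjusted p = 0.590 with an estimated correlation). SESN1 read 640 ± 63.9 (n = 3) against 453 ± 49.4 (n = 2), a log2 fold of 0.48, MDM2, the p53 ubiquitin ligase, had 0.53 and the nucleotide excision repair gene XPC 0.24. DDB2, another repair gene, had 1.11 with overlapping groups, since Aire replicate 3 (1269) lay below control replicate 2 (1298). The list also differed between the controls, with a median of -0.20 in control replicate 1 relative to control replicate 2, and without control replicate 1 the median log2 fold was 0.18.

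Immediate-early genes fell as a list. Of 27 measured members, 5 fell and 0 rose adjusted over the list alone, and 0 fell over all probe sets. MYC fell from 2785 ± 252 (n = 2) to 1747 ± 151 (n = 3), a log2 fold of -0.67, and the transcription factor genes KLF4, NR4A2 and JUN had -0.68, -0.62 and -0.39. The other probe set of KLF4 gave -0.14 and those of NR4A2 -0.15 and -0.17, while those of JUN gave -0.59 to -0.90. The probe sets that represent NR4A2 and JUN are of the kind that can cross-hybridise. The list's median was -0.18 (camera adjusted p = 1.96e-06), and its adjusted p = 0.590 with an estimated correlation. On probe sets of plain name, chosen after the data were seen, 15 members were left and 0 fell adjusted over the list alone. The probe sets of MYC, KLF4, NR4A2 and JUN are not among these. The median there was -0.18 (camera adjusted p = 0.00351).

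Genes of glycolysis and the hypoxia response were lower as a list, in a difference set by control replicate 1. Of 28 measured members, 0 rose and 0 fell adjusted over the list alone, and the median log2 fold was -0.21 (camera adjusted p = 1.31e-04, and adjusted p = 0.669 with an estimated correlation). The glucose transporter gene SLC2A3 read 276, 263 and 241 on the arrays labelled Aire and 764 and 280 on control replicates 1 and 2, and ANKRD37 read 161, 185 and 214 against 837 and 207. EGLN3, an oxygen sensor, had a log2 fold of -0.47 and HK1, a hexokinase, -0.20. Between the controls the list's median was 0.86 higher in control replicate 1. Without control replicate 1 the list turned to higher in the arrays labelled Aire (adjusted p = 0.0310), and without Aire replicate 3 the call was lost (0.0608).

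**Figure D3:**
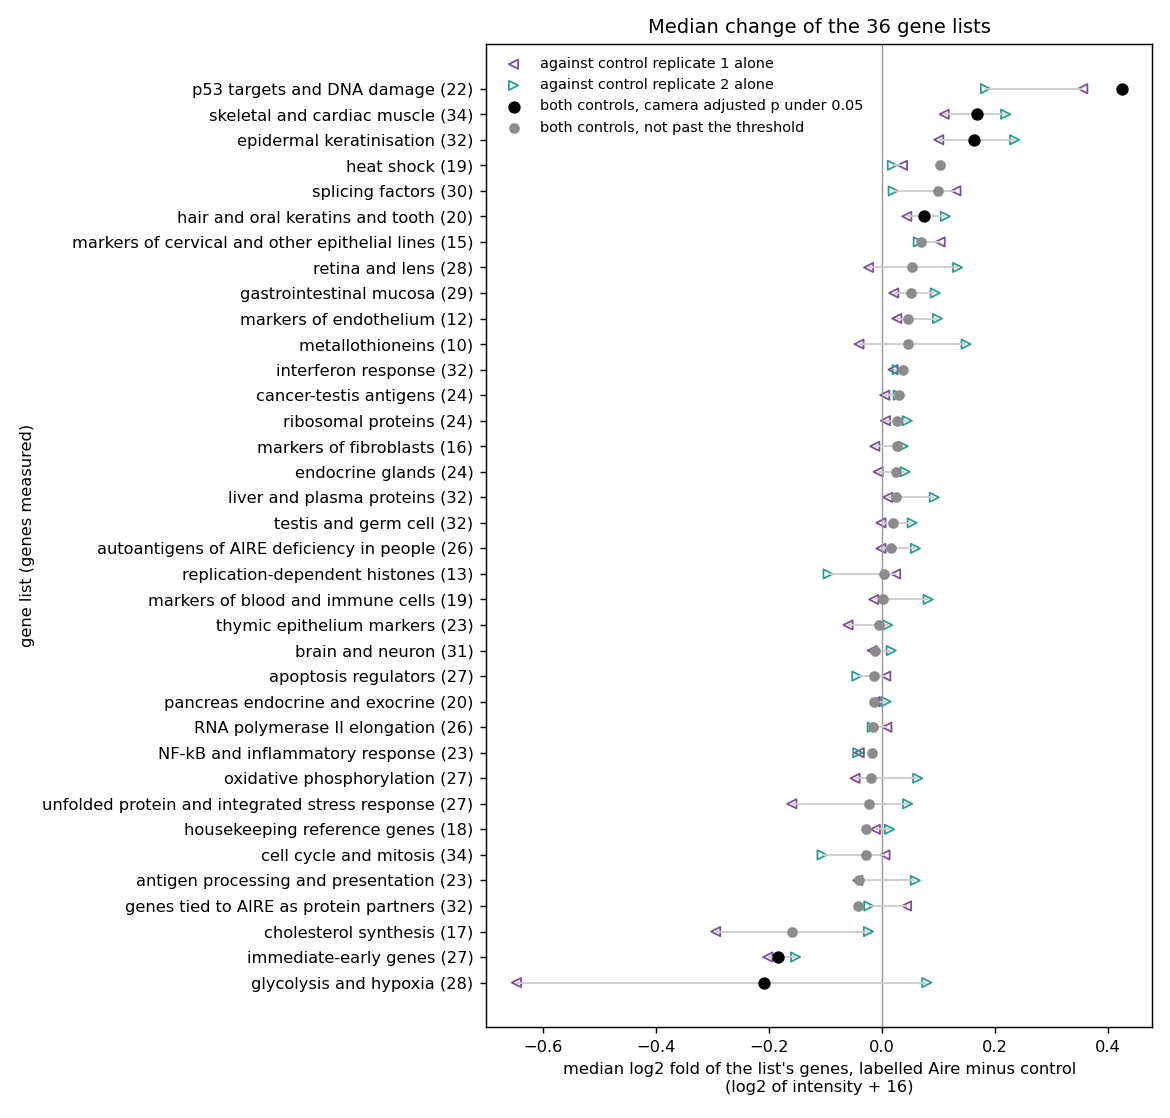
Median log2 fold of each of the 36 gene lists, arrays labelled Aire minus controls, with the number of measured genes in parentheses; black points passed camera at an adjusted p under 0.05, and open triangles are medians against each control alone. The glycolysis and hypoxia list runs from -0.65 against control replicate 1 to 0.08 against control replicate 2.

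The other tissue lists did not pass camera, with adjusted p among the 30 lists not called from 0.0519 to 0.971. Of 32 measured liver and plasma protein genes, 4 rose adjusted over the list alone, namely the apolipoprotein gene APOA2 (log2 fold 0.53), the haptoglobin gene HP (0.51), CYP1A2 (0.53) and the transferrin gene TF (0.79). The probe set of CYP1A2 is of the kind that can cross-hybridise and its other probe set gave 0.05, and the other 3 of TF gave 0.92, -0.01 and -0.06. Of 24 measured endocrine genes 2 rose adjusted over the list alone, the steroid side-chain cleavage enzyme gene CYP11A1 (0.99) and the growth hormone gene GH1 (0.72, on a probe set of the kind that can cross-hybridise). Of 28 measured genes of retina and lens 1 did, the crystallin gene CRYBA1 (0.97). No gene passed adjusted over the list alone among 32 of testis and germ cell (TEX101 0.41, LDHC 0.25), 24 cancer-testis antigens (PAGE4 0.32, MAGEA10 -0.28), 20 of pancreas (CHGB 0.54, PNLIP 0.26), 29 of gastrointestinal mucosa (FABP6 0.44, GAST 0.30) and 31 of brain and neuron (NEFH 1.01, DBH 0.42). The 3 GAGE probe sets that rose carry several symbols each, so they were not counted in the cancer-testis list. Of 26 measured autoantigens of AIRE deficiency in people, 3 rose adjusted over the list alone, CYP11A1, CYP1A2 (on the same probe set as above) and NLRP5 (0.50), and 1 fell, SOX9 (-0.37).

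Tissue-restricted genes as a class rose slightly. Of 306 measured members of the 11 tissue lists, 24 rose and 0 fell adjusted over the list alone, in 6 lists, counting each gene within its own list. The pooled median log2 fold was 0.05 (camera p = 2.32e-05), and p = 0.197 with an estimated correlation. This median was 0.03 without Aire replicate 3, 0.09 without control replicate 1 and 0.02 without control replicate 2. At an unadjusted p under 0.05, 46 tissue genes (15.0%) and 947 of 19469 other genes (4.86%) were higher, an odds ratio of 3.46 with a 95% interval of 2.45 to 4.79 (two-sided Fisher's exact p = 2.55e-11). In the same test 1 tissue gene and 598 other genes were lower (Fisher's exact p = 0.00193). At an adjusted p under 0.05 the counts were 1 and 4 (Fisher's exact p = 0.0750). Fisher's test counts genes as separate units, though all were read on the same 5 arrays. Its p and interval therefore do not measure the spread between cultures. Against control replicate 1 alone, which leaves out control replicate 2, the shares were 12.4% and 11.2% (Fisher's exact p = 0.523) and the camera p was 0.106, while against control replicate 2 alone they were 15.4% and 2.99% (Fisher's exact p = 2.31e-19).

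Among pathway lists that did not pass, a few members did within their list. Of 32 measured interferon response genes 3 rose adjusted over the list alone, ISG20 (0.81), USP18 (0.48) and IRF9 (0.48). Of 19 heat shock genes 1 fell, HSPB8, while the co-chaperone DNAJA1 had 0.41, and of 13 replication-dependent histone genes 1 fell, H1-2. No member passed within its list among genes tied to AIRE as protein partners (RANBP2 0.53, MBD1 0.21), the NF-kB and inflammatory response (CCL2 0.24, PTGS2 -0.32), the unfolded protein and integrated stress response (SESN2 0.76, CHAC1 0.77), cell cycle and mitosis (CCNE2 -0.42, CDK1 -0.32), apoptosis regulators (BCL2L1 -0.24, HRK -0.31), RNA polymerase II elongation (HEXIM1 0.71, POLR2A 0.40), splicing factors (SRSF7 0.46), ribosomal proteins (RPL32 0.11), oxidative phosphorylation (CYC1 -0.37, NDUFS3 0.24), antigen processing and presentation (HLA-E -0.31, PSMB10 0.47), cholesterol synthesis (NSDHL 0.34, INSIG1 -0.72), metallothioneins (MT1G 0.18) and housekeeping reference genes (EIF2B1 0.46).

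Markers of other cell types gave no list that passed. Of 23 measured thymic epithelium markers 2 rose adjusted over the list alone, KRT14, which is also on the epidermal list, and the chemokine gene CCL19 (0.55). Of 19 markers of blood and immune cells 1 did, LCK (0.70), of 12 of endothelium VWF (0.58) and of 15 of cervical and other epithelial lines ELF3 (0.49). Other probe sets of these genes gave 0.11 for LCK, -0.10 for VWF and -0.07 and 0.05 for ELF3. Of 16 fibroblast markers 0 did, with ACTA2 at 1.05 and VIM at -0.28. The camera adjusted p of these 5 lists ranged from 0.118 to 0.711.

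Genes of low level did not move in a direction of their own that held across the arrays. Of the 5 genes that rose, 1 (S100A8) lay in the lowest of 3 bins of mean level, 4 in the middle and 0 in the highest, and with 0 falls the planned test of direction was void. In a count added after the data were seen, of genes with an unadjusted p under 0.05, 77.9% in the lowest bin and 61.4% in the highest were higher in the arrays labelled Aire (two-sided Fisher's exact p = 1.73e-06). Without Aire replicate 3 the shares were 44.3% and 68.3% (Fisher's exact p = 2.73e-19), the other way round. With array quality weights they were 68.5% and 66.4% (Fisher's exact p = 0.504). These tests too count genes of the same arrays as separate units and do not measure the spread between cultures.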

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

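The block on the spike-in groups, the counts by level at an unadjusted p, the lists and tissue genes on probe sets of plain name or with 1 gene per run of neighbours, and the tissue genes without those called were chosen after the data were seen. The 15 probe sets that rose all kept a positive log2 fold wherever they were tested, with medians from 1.37 to 2.20. Since each was higher on every array labelled Aire than on both controls, leaving out an array or adding a block could not turn the sign. The kept sign is therefore no separate support, and what changed was how many passed. The count of probe sets and genes that rose was 27 and 8 with a pseudocount of 1, 0 and 0 with a pseudocount of 64, and 24 and 8 with a variance trend. It was 25 probe sets with array quality weights, and 2 genes with the mean of all probe sets. At an unadjusted p with a fold of at least 2 it was 97 and 49, beside 7 and 2 that fell. Leaving out 1 array gave 0 to 422 probe sets and 0 to 240 genes that rose, and 0 to 173 and 0 to 74 that fell. An arm left with 1 control was assumed to vary like the other arm. Under quantile normalization, median centring and robust eBayes the counts stayed within 1.5 times. The log2 fold of AIRE stayed between 0.02 and 0.35.

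With the spike-in block 2 probe sets and 0 genes rose, 0 in the lowest bin. The median log2 fold of the 15 was 1.83 with a median standard error of 0.09, against 1.86 and 0.11 without the block. The fit with the block had 1 residual degree of freedom less, and why fewer passed was not tested. With this block 4 lists rose and 2 fell, the tissue lists pooled had a p of 6.86e-05, and at an unadjusted p 76.4% of the genes in the lowest bin and 50.3% in the highest were higher (Fisher's exact p = 1.69e-17).

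In the lowest bin 1 gene rose. This count was 0 without dim probe sets, which takes out most of that bin. It was also 0 with a pseudocount of 64, with the replicate block or with the mean of all probe sets. It was 2 with array weights, 3 with a pseudocount of 1 or a trend, and 4 with bins at the median (1 in the upper). Leaving out 1 array gave 0 to 5 rises and 0 to 1 falls there, and 0 to 131 and 0 to 41 in the highest bin.

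Of the gene lists 4 rose and 2 fell. An estimated correlation gave 0 and 0, as did fry, and the mean of all probe sets gave 9 and 4. Leaving out 1 array gave 3 to 10 that rose and 1 to 3 that fell. On probe sets of plain name 4 rose and 2 fell, with an adjusted p of 0.0368 for the hair list, and with 1 gene per run of neighbours that share their first 3 letters 3 rose and 2 fell, as the hair list lost its call (0.165). The adjusted p of the glycolysis and hypoxia list, in the turned direction, was 0.0310 without control replicate 1, and in the same direction as with all arrays it ran from 2.72e-15 without control replicate 2 to 0.0608 without Aire replicate 3. For the tissue lists pooled p was 0.197 with an estimated correlation, 8.26e-09 without control replicate 1 and 0.106 without control replicate 2. On probe sets of plain name it was 1.32e-04, with 1 gene per run of neighbours 4.59e-04, and without the genes called it was 3.67e-05.

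With the replicate block 0 probe sets and 0 genes rose (smallest adjusted p 0.260), and the hair list had an adjusted p of 0.0908. Replicate number 3 occurs only among the arrays labelled Aire, so this block takes up that array. The log2 folds are therefore those without Aire replicate 3, with a hair list median of 0.02 in both fits. The block is not a separate alternative, and it leaves fewer residual degrees of freedom. At an unadjusted p with this block 52.7% of the genes in the lowest bin and 73.3% in the highest were higher (Fisher's exact p = 8.37e-12). This is the reverse of 77.9% and 61.4% without the block. Without dim probe sets the shares were 79.2% and 65.8% (Fisher's exact p = 0.268). The lowest bin then held only 19 higher and 5 lower genes, so this test cannot tell whether the difference was lost. Only replicate numbers 1 and 2 occur in both groups, and the deviations of same-numbered arrays correlated at 0.0948 and -0.109. With 2 controls the deviations of the controls mirror each other, so these values are not separate. They gave no sign of pairs but cannot exclude them.

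Of 162 named genes under all alternatives, 2547 of 2560 values kept their direction. Most of these genes were chosen by separate groups or by the smallest p of their list, so few could turn. The count is therefore no separate support. The values that turned lay near 0, and the cause was not tested. With all arrays and 1 probe set per gene, SLC30A1 had stood at 0.33, ITGAM at -0.31, MT1X at -0.29 and ROBO4 at -0.23. INS stood at 0.019 under the replicate block and without Aire replicate 3 and at 0.027 without control replicate 1, against -0.11 without control replicate 2. IVL stood at -0.041 under the replicate block and without Aire replicate 3, at -0.016 without control replicate 2 and at -0.00721 with array quality weights, against 0.10 without control replicate 1. The mean of all probe sets turned MBD1 (-0.00813), NUMA1 (-0.018), ITGAM (0.037) and ROBO4 (0.012), and leaving out control replicate 1 turned SLC30A1 (-0.027, against 0.69 without control replicate 2) and MT1X (0.048, against -0.64).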

Other observations

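The genes named first below, the splits of the arrays, the rise against control replicate 2 alone, the contrast of the controls, the block on the spike-in groups, the tissue genes on probe sets of plain name or with 1 gene per run of neighbours and the removal of growth hormone pairs were chosen after the result was seen.

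Among 49 genes higher by at least 2-fold at an unadjusted p, of which 5 passed, several have known tissue roles; they were picked by reading and stand for no tested group. TCHH, which encodes a structural protein of the hair root sheath, read 104 ± 24.3 (n = 3) on the arrays labelled Aire and 29.4 ± 2.60 (n = 2) on the controls, a log2 fold of 1.38 (limma adjusted p = 0.292). ZNF750, a transcription factor of keratinocyte differentiation, had 1.34 (adjusted p = 0.463), PPL, which encodes periplakin of the cornified envelope, 1.19 (0.400), PDZK1, a scaffold protein of kidney and gut brush borders, 1.80 (0.356) and FCGBP, a mucus protein, 1.18 (0.339). The inflammasome-related genes NLRP7 and NLRP2 had 1.52 and 1.14 (0.264 and 0.279). The genes lower by at least 2-fold at an unadjusted p were RHOB, a small GTPase (-1.08), and SEC24D, a coat protein of transport vesicles (-1.07). Both were higher in control replicate 1 (5487 and 387) than in control replicate 2 (2881 and 180).

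Between the controls other lists also had different medians, as values of single arrays without a test. The median of cholesterol synthesis genes was 0.27 higher in control replicate 1, that of metallothioneins 0.24 higher and that of splicing factors -0.18. NEFM, a neurofilament gene, read 5604 on control replicate 1 and 2550 on control replicate 2, and ATF7IP read 202 and 687.

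The pooled tissue genes were higher in the arrays labelled Aire. Probe sets shared by near-identical genes and a shift of all dim probe sets were argued against as the whole cause, since the rise was present on genes whose probe sets have plain names (limma camera, n = 213 genes, p = 1.32e-04) and with 1 gene per run of neighbouring paralogs (p = 4.59e-04), and the median lay at percentile 100 of 10000 random lists matched on level. The hybridisation batch that the spike-ins mark was argued against as the whole cause, since the rise was present with a block on it (limma camera, n = 306 genes, p = 6.86e-05). These camera tests used the preset correlation of 0.01, and the random lists did not keep the correlation of the tissue genes. They weigh these causes only as far as the rise holds at that setting. A hypothesis that remains is that the plasmid with Aire raised tissue-restricted transcripts, but the AIRE probe set did not check the label, and the call was lost with an estimated correlation (p = 0.197, n = 306 genes) or without control replicate 2 (p = 0.106). RNA integrity, whose 3' over 5' sign was higher on every array labelled Aire (1.04, 1.06 and 1.62) than on the controls (0.80 and 0.92) and so follows the groups, stays open as a cause, as do other differences in array batch or in culture.

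Control replicate 1 differed most from the other arrays. Lower RNA integrity was argued against, since its 3' over 5' value of 0.805 was the lowest of the 5 arrays, where poorer RNA would raise it; the range test as written also counted a low value as a sign, which was wrong for that reason. A culture with less oxygen or glucose may be a cause but was not decided: the glycolysis and hypoxia list lay at percentile 100 of matched lists between the controls, yet this compares single arrays and restates the high genes that prompted it. Whether this array contributes to the rises of the 15 probe sets was not decided either, since their median against control replicate 2 alone, 0.995 of that against both controls, is near 1 by selection, as a small p needs controls that are alike.

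Of the 10 splits of the arrays into 3 and 2, too few for a share under 0.05, 1 gave as many rises as the real 15, namely the real one, and the highest other count was 0. At an unadjusted p, 3301 probe sets differed between the real groups, 6879 between Aire replicates 1 and 2 and the rest, and 6764 between Aire replicate 3 with control replicate 2 and the rest. This points to a structure of the arrays, and the last split is the one the spike-ins form. With a block on it 2 of the 15 probe sets passed, but all 15 had a positive log2 fold. Their median was 1.83 against 1.86 without the block, with a median standard error of 0.09 against 0.11. The fit with the block had 1 residual degree of freedom less, and why fewer passed was not tested. The similar fold is near fixed by selection, as a small p needs arrays that are alike within each group. It does not decide whether this structure contributes to their rises.

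Genes higher in the arrays labelled Aire lay next to each other more often than shuffled genes. Among 265 genes with an unadjusted p under 0.01 there were 18 neighbouring pairs against 3.55 on average (permutation p = 1e-04, the smallest that 10000 shuffles can give), among them KRT33A with KRT33B and KRT31, KRT9 with KRT14 and KRT16, and NLRP7 with NLRP2. Cross-hybridisation between paralogs of a cluster may be a cause: without pairs that share their first 3 letters 8 pairs were left (permutation p = 0.0136), but this rule missed the growth hormone and placental lactogen genes, and without these 6 were left (permutation p = 0.0904). A hypothesis of shared control over whole clusters was not separated from it. The 103 lower genes gave 0 pairs, where shuffled genes gave 0.53 on average, so they were too few to compare.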
